A study of Mus musculus with 5 samples.

How the data were processed

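Single-nucleus RNA sequencing of hippocampal nuclei was deposited as 1 count matrix for each of 5 libraries, 1 library per group. The deposited values are counts of unique molecular identifiers (UMIs), whole numbers per gene and barcode, over 32285 genes. The submitters' processing notes name Cell Ranger 8.0, Seurat and the genome build mm10. The barcode lists hold 1531592 barcodes for wild type vehicle, 1513696 for transgenic vehicle, 1507458 for transgenic THC, 1305886 for transgenic celecoxib and 1489565 for transgenic celecoxib and THC, but 6203, 8134, 7975, 8101 and 7785 of them hold any count. How barcodes were chosen, and whether counts were corrected for free RNA before deposit, is not given in the sources used here. Of the 32285 gene identifiers, 32158 matched the GENCODE annotation of GRCm38, from which positions were taken.

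Nuclei were barcodes with at least 500 detected genes and at most 5% mitochondrial UMIs. Scrublet was run through scanpy 1.11.5, and the nuclei with the highest scores were removed as putative doublets in each library, the share removed being 0.8% per 1000 nuclei. This removed 181 nuclei from wild type vehicle, 324 from transgenic vehicle, 313 from THC, 361 from celecoxib and 269 from celecoxib and THC. Over the 5 libraries, 28439 nuclei of 38198 barcodes with counts were kept. Counts were scaled to 10000 per nucleus and log transformed, 2000 variable genes and 30 principal components were used, and a graph of 15 neighbours was clustered by the Leiden method at resolution 1 with seed 1, which gave 34 clusters. Clusters were named from 21 fixed marker sets when at least 3 markers of a set stood at least 1 log2 unit above the other clusters, with 20 counts per 1000000 (CPM) added. A cluster was left unnamed, and used in no comparison of genes, when it met no set, when another set reached 0.6 of the mean of the best set, when more of its top 10 genes belonged to another set, or when it was shallow and none of those genes was a marker.

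For each library and cell class the UMIs of all nuclei were summed and given as CPM of the class total, with an exact Poisson 95% interval. Ratios had 0.5 UMI added to each count and an exact conditional binomial interval. Shares of nuclei had an exact Clopper-Pearson binomial interval. All intervals and limits cover counting error only. A count of 0 was read as allowing up to 3 UMIs, and a fold against a count of 0 was given as a lower bound against those 3 UMIs. With 1 library per group no test between groups was made and no number of changed genes is given.

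The comparisons were transgenic vehicle against wild type vehicle, each of the 3 treated transgenic libraries against transgenic vehicle, and celecoxib and THC against each drug alone. The groups, comparisons, lists, markers and the rule for naming genes were set before the data were examined. The rule named, in granule neurons of the dentate gyrus (DG), CA1 pyramidal neurons, astrocytes, oligodendrocytes and microglia, the first 3 genes higher and the first 3 lower for each of the first 4 comparisons. They were ordered by the interval bound nearest to no change, among genes with at least 50 UMIs over the 2 libraries, an absolute log2 ratio of at least 1 and a level of at least 0.2 of that in the class where the gene is highest. Mitochondrially encoded, Rpl, Rps and hemoglobin genes, Malat1, Xist, Tsix and Y-linked genes were left out of the ranking. No gene was named in a class with under 50 nuclei in either library. For celecoxib and THC against each drug alone, 1 gene in each direction was named per class. The rule also named 2 to 4 members of each list, those with the largest and most deeply counted differences, and the genes of the label check, which were App, Thy1, Xist and 4 Y-linked genes. For lists near no change the median alone is given, and which further members are printed was chosen after values were seen.

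There were 19 lists. Read in microglia were disease-associated microglia, homeostatic microglia, complement, inflammatory cytokine and NF-kB, interferon response and antigen presentation genes. Disease-associated and homeostatic astrocyte genes were read in astrocytes, and disease-associated oligodendrocyte genes and myelin genes in oligodendrocytes. Glutamatergic synapse, presynaptic release, activity-induced and amyloid precursor processing genes were read in DG granule and CA1 neurons. Endocannabinoid system, prostaglandin and eicosanoid, cholesterol synthesis, oxidative phosphorylation, and heat shock and unfolded protein genes were read in the classes for which they are reported. A member was measured with at least 20 UMIs over the 2 libraries, and was counted as higher or lower at 1.5-fold or more with an interval excluding 1. The percentile of a list median was taken among 10000 random lists of the same size matched on level in the class. The percentile describes these libraries and is not a test.

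To follow genes that differed by genotype into the treated libraries, nuclei of transgenic vehicle were split at random into 2 parts. Part A chose the genes against wild type and part B was the reference for the treated libraries, so that counting error in the reference was not shared.

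The procedure was tested on simulated Poisson counts around a shared level, without differences between animals, clusters or sexes. The results below thus cover counting error only. In DG granule neurons, with 10511 genes, the size rule found 99 of 100 genes changed 3-fold and 100 of 100 changed 6-fold, and 8 of 10311 unchanged genes passed it. In microglia, with the class totals of THC and transgenic vehicle and 3175 genes, it found 97 of 100 at 3-fold and 100 of 100 at 6-fold. There 10 of 2975 unchanged genes passed.

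Alternatives were minimums of 200 and 1000 genes, at most 1% mitochondrial UMIs, no removal of doublets, resolution 2, median-of-ratios size factors, a mean over nuclei, members with at least 50 UMIs and an unsplit reference. Chosen after seeing the data were nuclei with Xist alone, nuclei with Y-linked UMIs alone, lists without members near 0 in 1 library, neurons without the shallow clusters, inhibitory neurons without the cluster with the lowest ratio of celecoxib to vehicle nuclei (the uneven cluster), and a wild type library split too. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.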

Results

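Nuclear RNA of the mouse hippocampus was measured by droplet-based single-nucleus RNA sequencing in 5 libraries, 1 for each group. The groups were wild type mice given vehicle and transgenic mice given vehicle, THC, celecoxib, or celecoxib together with THC. The transgenic mice are called an APP line in the titles and 5xFAD, a line with transgenes driven by Thy1 sequences, in the genotype labels. THC is tetrahydrocannabinol, an agonist of the cannabinoid receptor encoded by Cnr1, at a dose called low in the series title. Celecoxib inhibits cyclooxygenase-2, the prostaglandin-forming enzyme encoded by Ptgs2. Doses, ages, sexes and the number of mice per library are not given in the sources used here.

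The deposited counts came to 32594318 UMIs for wild type vehicle, 38111109 for transgenic vehicle, 43988357 for THC, 39557479 for celecoxib and 41052301 for celecoxib and THC. After filtering, 4575, 6036, 5942, 6354 and 5532 nuclei remained in these libraries, in this order. The median nucleus held 4169, 4181.5, 5111.5, 3820.5 and 4981 UMIs. There were no replicates, so no difference between libraries has a replicate check, and every interval covers counting error only.

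Most classes found were those of hippocampal tissue, beside choroid plexus cells, ependymal cells, fibroblasts and a few thalamic or habenular neurons from next to it. DG granule neurons made up 26.4% of nuclei in wild type vehicle, 23.9% in transgenic vehicle, 24.0% in THC, 22.9% in celecoxib and 22.8% in celecoxib and THC. CA2/CA3 pyramidal neurons made up 8.28%, 7.50%, 9.19%, 6.66% and 9.00% of nuclei in the same order and inhibitory neurons 9.64%, 10.1%, 7.57%, 6.04% and 8.82%. CA1 pyramidal neurons made up 10.4% in celecoxib and 12.1% to 14.8% in the other libraries. At resolution 2, where part of the nuclei nearest to CA1 lay in unnamed clusters, their share was 5.56% in celecoxib and 8.02% in transgenic vehicle. Nuclei in unnamed clusters made up 16.8%, 18.0%, 14.1%, 15.2% and 19.8%.

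**Figure D1:**
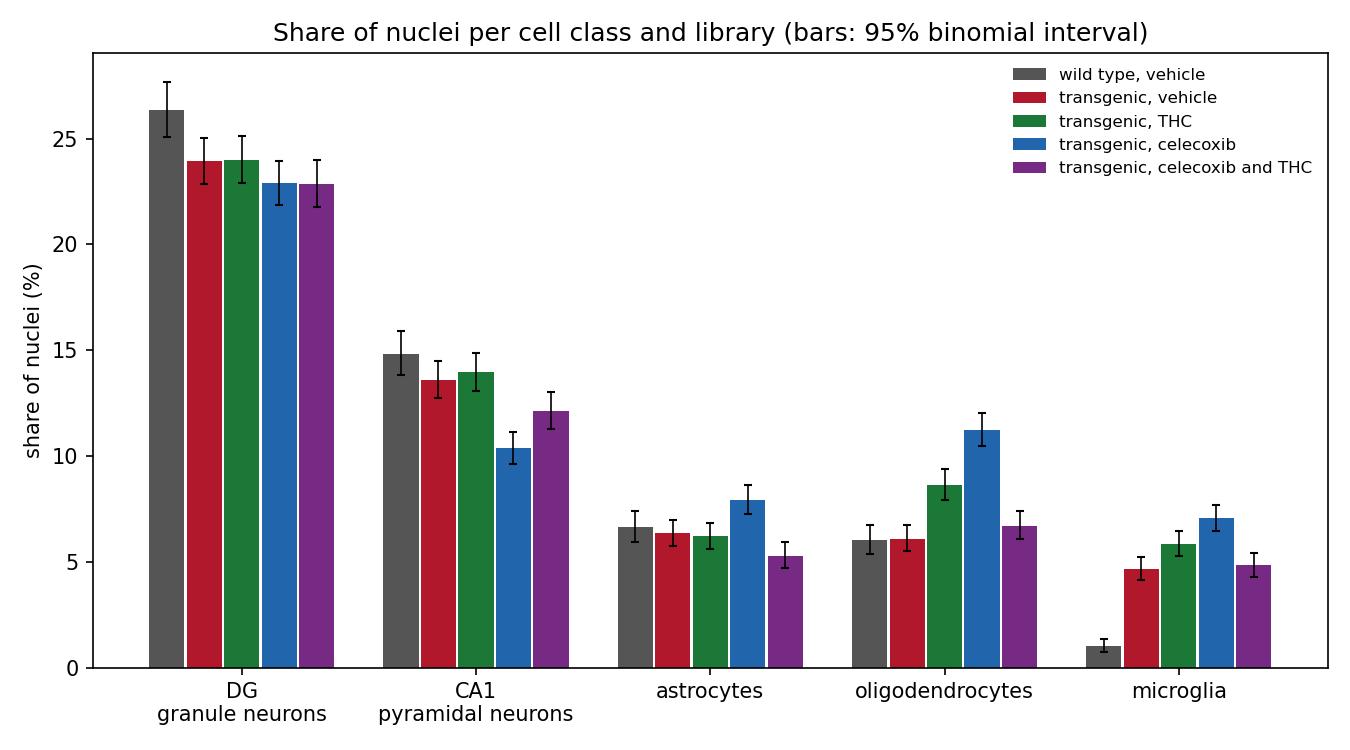
Share of nuclei (%) on the vertical axis for 5 cell classes, with 1 bar per library and exact 95% binomial intervals. The microglial bar is 1.01% in wild type vehicle and between 4.67% and 7.05% in the 4 transgenic libraries.

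Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579, build mm10), whose promoter drives the transgenes, separated the genotype labels. In CA1 neurons it stood at 28.9 CPM in wild type vehicle and at 214, 268, 186 and 239 CPM in transgenic vehicle, THC, celecoxib, and celecoxib and THC. App stood at 459, 468, 522, 459 and 525 CPM over neurons of all named classes.

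Sex-linked RNA differed between the libraries. Nuclei with Xist, the RNA of the inactive X chromosome, and no Y-linked UMI made up 37.2% of wild type vehicle, 96.6% of transgenic vehicle, 44.3% of THC, 75.4% of celecoxib and 0.0542% of celecoxib and THC. Nuclei with a Y-linked UMI and no Xist made up 29.4%, 0% (which allows a share of up to 0.0497%), 31.6%, 12.6% and 71.7%. Nuclei with both made up 17.1%, 0.0828%, 12.7%, 5.24% and 0.578%, so these calls also hold RNA of other nuclei or doublets. Nuclei with neither made up 16.4%, 3.36%, 11.3%, 6.72% and 27.6%. Thus, among nuclei with such UMIs, transgenic vehicle held those with Xist almost alone, and celecoxib and THC those with Y-linked RNA almost alone. The other 3 libraries held both kinds.

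**Figure D2:**
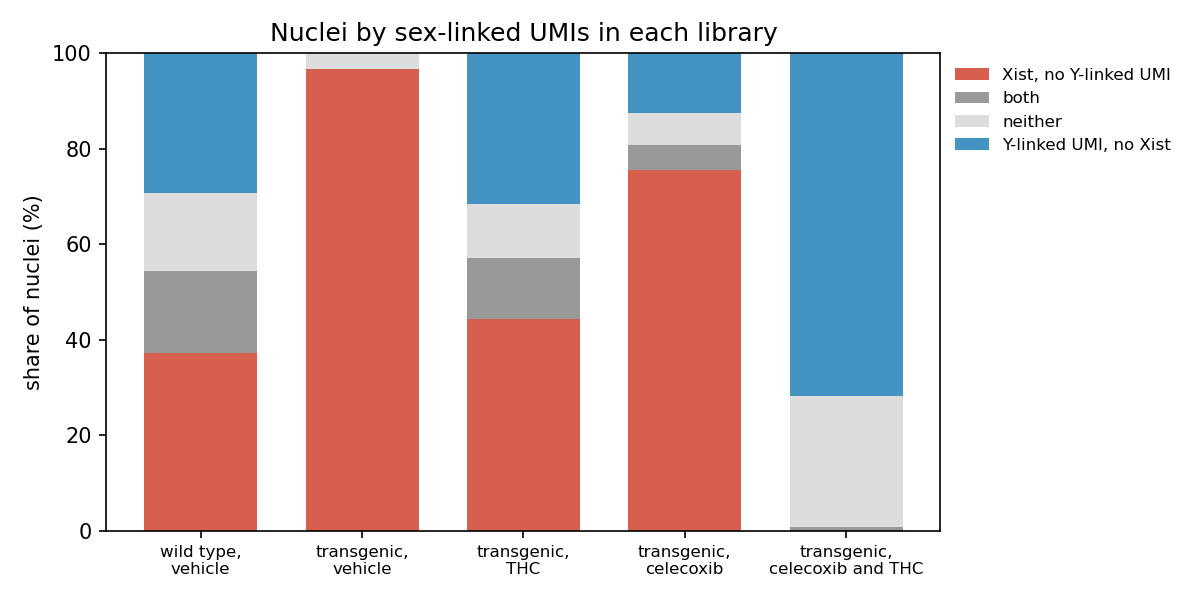
Share of nuclei (%) on the vertical axis in each of the 5 libraries, stacked by which sex-linked UMIs a nucleus held. Nuclei with Xist alone make up 96.6% of transgenic vehicle and 0.0542% of celecoxib and THC.

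The first comparison, transgenic vehicle against wild type vehicle, asked how the hippocampus of the transgenic mice differs without treatment. Microglia, the resident phagocytes of the brain, made up 4.67% of nuclei (4.15% to 5.23%) in transgenic vehicle and 1.01% (0.737% to 1.34%) in wild type vehicle, 4.65-fold more (3.39 to 6.49). Their RNA differed as well. Disease-associated microglia genes, which include lipid-handling and lysosomal genes, had a median log2 ratio of 2.20 (1.93 to 3.12), with 19 of 23 measured members higher and 0 lower, at percentile 100 of random lists. Apoe, a lipid carrier (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), stood at 2708 CPM in transgenic vehicle and at 0 UMIs in wild type vehicle. This 0 is of the kind found for genes near 0 in 1 class of 1 library, so no fold is given for it. Without members of that kind, a setting chosen after seeing the data, the list median was 1.99. At resolution 2 most microglia of the 2 libraries lay in different clusters, so the class ratios set different mixes of microglial states side by side. Homeostatic microglia genes had a median of -0.42 (-0.58 to -0.21), with 1 of 16 members higher and 6 lower.

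Other disease-associated members followed the same direction. Trem2, a lipid receptor, was 4.60-fold higher (2.23 to 13.8) at 399 against 80.3 CPM, Myo1e stood at 1234 CPM against 2 UMIs in wild type, also a value near 0, and the protease Ctsd was 3.87-fold higher (2.51 to 6.66). With the 7 members that had 0 UMIs in 1 library set to their limit, the list median was 1.76. This lies below the interval given above, which leaves that limit out. Among homeostatic genes, Fcrls stood at 34.6 against 187 CPM and Tmem119 at 90.5 against 187 CPM. Interferon response genes had a median of 1.64 (1.21 to 2.83), with 6 of 11 higher and 0 lower. Among them Trim30a, which is induced by interferon, stood at 460 against 147 CPM. Antigen presentation genes had a median of 1.05 (0.58 to 2.28), with 3 of 6 higher, or 0.83 with members at 0 set to their limit, and H2-K1 stood at 245 against 66.9 CPM. Complement genes had a median of 0.17 with 1 of 7 higher and 1 lower, and inflammatory cytokine and NF-kB genes one of 0.34 with 2 of 9 higher.

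In astrocytes, disease-associated genes were higher in transgenic vehicle, with a median of 0.87 (0.65 to 1.07), 10 of 16 members higher and 0 lower. Gfap, the intermediate filament of reactive astrocytes (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), was 4.20-fold higher (3.35 to 5.35) at 521 against 124 CPM. At resolution 2 the astrocytes formed more than 1 cluster, in proportions that differed between the libraries. In wild type vehicle, transgenic vehicle, THC, celecoxib, and celecoxib and THC, a cluster led by Gfap held 15, 69, 46, 125 and 38 nuclei. The main astrocyte cluster held 293, 314, 332, 381 and 258. Class ratios of astrocytes, also those of the treated libraries, thus set different mixes side by side. The complement gene C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882) was 4.98-fold higher (3.77 to 6.78) in astrocytes and 3.90-fold higher (3.01 to 5.17) in oligodendrocytes. Cholesterol synthesis genes of astrocytes were lower, with a median of -1.10 (-1.40 to -0.82), 11 of 16 members lower and 0 higher. The neuronal marker Meg3 stood in these astrocytes at 10.5 CPM (4.54 to 20.7), against 78.7 CPM (59.8 to 102) in wild type, and Snap25, another neuronal marker, had 3 UMIs against 1. Hmgcs1, an early enzyme of the pathway (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260), stood at 35.5 against 102 CPM and Sqle, a later enzyme, at 5.26 against 32.6 CPM, where the value of Sqle in transgenic vehicle is near 0. Heat shock and unfolded protein genes of astrocytes had a median of -1.11 (-1.71 to -0.64), with 4 of 8 lower. Of these the chaperone Hspa8 had 2 UMIs in transgenic vehicle and was 9.70-fold lower (2.93 to 104). Homeostatic astrocyte genes had a median of -0.26 with 0 of 17 past 1.5-fold.

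In oligodendrocytes, disease-associated genes had a median of 0.38, with 3 of 6 higher, among them Il33 at 533 against 334 CPM. Myelin genes, which insulate axons, had a median of -0.05, cholesterol synthesis genes one of -0.64 with 2 of 4 lower, oxidative phosphorylation genes one of 0.54 over 3 members and heat shock genes one of -0.19 over 10. Meg3 stood in these nuclei at 77.7 CPM (57.5 to 103), against 182 CPM (149 to 220) in wild type, and Snap25 had 5 UMIs against 3. In astrocytes oxidative phosphorylation genes had a median of -0.30, endocannabinoid genes one of -0.32 and prostaglandin genes one of 0.38 over 2 members.

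In neurons, glutamatergic synapse genes had a median of -0.11 in DG and -0.17 in CA1, and presynaptic release genes of -0.05 and 0.0023. Activity-induced genes, which neurons transcribe after firing, had a median of 0.04 in DG and of -0.28 (-0.41 to -0.15) in CA1 neurons, where 4 of 16 were lower. Nr4a1 stood there at 21.6 against 44.6 CPM and Per1 at 8.52 against 19.2 CPM. Endocannabinoid genes had medians of -0.03 in DG, -0.13 in CA1, -0.09 in inhibitory neurons and 0.14 in microglia. Prostaglandin genes had medians of 0.16 in DG, 0.33 in CA1 and -0.17 in microglia. Amyloid precursor processing genes had medians of -0.07 in DG and -0.04 in CA1, with Thy1 as the member that was higher in both. Oxidative phosphorylation genes had medians of 0.07, 0.14 and -0.04 in DG, CA1 and microglia, and heat shock genes of -0.14, -0.24 and 0.20.

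By the naming rule, Thy1 was 4.07-fold higher in DG (3.33 to 5.03) and 7.37-fold higher in CA1 neurons (6.25 to 8.81). Also higher were Mcmdc2 (16.6 against 3.59 CPM) and Dact2 in DG, Gm12130 in CA1 neurons, Ddx60 in astrocytes (68.4 against 6.79 CPM) and Snx12 and 7630403G23Rik in oligodendrocytes. Lower were Rab5if, D330041H03Rik and Ctdnep1 in DG and Gm21887, Gm33524 and Sema6c in CA1 neurons, by 2.28-fold to 2.77-fold. Fth1, Disp1 and Tmem167 were lower in astrocytes and Serbp1, Zswim5 and Mtx2 in oligodendrocytes. For Mcmdc2, Snx12, 7630403G23Rik and the lower genes of DG, astrocytes and oligodendrocytes, transgenic vehicle was the library farther from the other 3. Gm12130 and Ddx60 in wild type and Fth1, Serbp1 and Mtx2 in transgenic vehicle were near 0 in 1 class of 1 library. No microglial gene was named, since wild type vehicle held 46 microglia.

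Transgenic vehicle held 96.6% nuclei with Xist alone and wild type vehicle 37.2%, so genotype and sex makeup differed together. Of the genes named above, Snx12 and Gm21887 lie on the X chromosome. Over nuclei with Xist alone, a setting chosen after seeing the data, the activity-induced median in CA1 neurons was 0.20 in place of -0.28. With a minimum of 1000 genes the microglial shares were 0.632% in wild type and 2.01% in transgenic vehicle.

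The second comparison, THC against vehicle in transgenic mice, asked what the cannabinoid alone goes with. Cholesterol synthesis genes of astrocytes had a median of 0.57 (0.27 to 0.86), at percentile 99.8 of random lists, with 3 of 13 members higher and 0 lower, Hmgcs1 at 80.9 against 35.5 CPM. Meg3 went the other way in these astrocytes, at 1.35 CPM (0.0341 to 7.51) against 10.5 CPM (4.54 to 20.7). Its value with THC, of 1 UMI, was itself near 0 in 1 class of 1 library. Heat shock and unfolded protein genes of astrocytes had a median of 0.97 (0.34 to 1.52), at percentile 99.2, with 4 of 9 higher, among them the chaperone Hsp90b1 at 41.8 against 21.0 CPM. Disease-associated astrocyte genes had a median of -0.31 (-0.49 to -0.14), with 3 of 17 members higher and 4 lower. It was -0.54 without doublet removal and -0.61 as a mean over nuclei. C4b was 1.63-fold lower (1.35 to 1.98), while Apoe was 1.71-fold higher (1.55 to 1.88) and Clu, another lipid carrier, 1.88-fold higher (1.56 to 2.28). In CA1 neurons Egr1, an immediate-early transcription factor (ENSMUSG00000038418, chromosome 18, 34859823 to 34864984), was 4.63-fold lower (3.11 to 7.26) at 3.92 against 18.4 CPM.

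Activity-induced genes had a median of -0.30 (-0.42 to -0.16) in CA1 neurons, with 6 of 17 lower and 0 higher. A shallow cluster made up 15.4% of these neurons with THC and 20.5% with vehicle. Without it, a setting chosen after seeing the data, the median was -0.19, and without doublet removal it was -0.47. Npas4 stood at 4.31 against 10.7 CPM and Arc, a synaptic plasticity gene, at 4.70 against 8.52 CPM. In DG neurons the same list had a median of 0.13, with Nr4a2 at 6.56 against 3.20 CPM. Microglia made up 5.84% of nuclei (5.26% to 6.47%), 1.25-fold more than with vehicle (1.07 to 1.47), oligodendrocytes were 1.42-fold more (1.24 to 1.62) and inhibitory neurons 1.33-fold fewer.

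Disease-associated microglia genes had a median of -0.12, with 1 of 28 higher and 3 lower. Lpl, a lipase, stood at 83.1 against 136 CPM and the adaptor Tyrobp at 162 against 247 CPM. Homeostatic microglia genes had a median of 0.11, complement genes of -0.10, inflammatory genes of -0.07 and interferon response genes of -0.17 with 0 of 15 past 1.5-fold. Antigen presentation genes had a median of -0.54 (-0.83 to -0.23), with H2-K1 at 134 against 245 CPM the 1 of 8 members past 1.5-fold. Meg3 had 0 UMIs in these microglia and 11 with vehicle. Homeostatic astrocyte genes had a median of 0.19, disease-associated oligodendrocyte genes of -0.19 and myelin genes of 0.10. Glutamatergic synapse genes had medians of -0.04 in DG and -0.05 in CA1 neurons, presynaptic genes of 0.03 and -0.05 and amyloid precursor processing genes of -0.06 and -0.08.

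Endocannabinoid genes had medians of -0.09 in DG, -0.01 in CA1, 0.11 in inhibitory neurons, 0.38 in astrocytes and -0.03 in microglia. In astrocytes the hydrolase genes Abhd6 and Abhd12 stood at 86.3 against 40.8 CPM and at 79.6 against 30.2 CPM. In inhibitory neurons Cnr1 stood at 171 CPM with THC and 121 CPM with vehicle, beside 165 CPM in wild type. Prostaglandin genes had medians of 0.20 in DG, -0.18 in CA1, -1.57 over 2 members in astrocytes and 0.12 in microglia. Cholesterol synthesis genes had a median of -0.14 in oligodendrocytes. Oxidative phosphorylation genes had medians of -0.08, -0.18, 0.18, 0.30 and -0.23 in DG, CA1, astrocytes, oligodendrocytes and microglia, and heat shock genes of -0.24, -0.03, -0.47 and 0.39 in DG, CA1, oligodendrocytes and microglia.

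By the naming rule, DG neurons held more Atp6v0c, a proton pump subunit (ENSMUSG00000024121, chromosome 17, 24163866 to 24169702), at 33.5 against 7.27 CPM and 4.57-fold higher (3.40 to 6.36), and more Rnasek and F13a1. They held less Wbp11, a splicing factor gene (ENSMUSG00000030216, chromosome 6, 136813654 to 136828233), 3.67-fold lower at 20.7 against 76.3 CPM, and less Mcmdc2 and Dnase1l2. In CA1 neurons Epyc, Sorbs2os and Gm26910 were higher by 2.10-fold to 3.53-fold, and Mcmdc2 and AC149090.1 lower. Higher in astrocytes were Clstn1, Fth1 and Agk, in oligodendrocytes Stimate, Tmbim6 and Myef2, and in microglia Atp6v1h, Thoc1 and Zfp322a. Lower in astrocytes were Hjurp, Gm29683 and Orc4, in oligodendrocytes Fkbp15, Snx12 and Chka, and in microglia Gtf3c2, Atp6v0c and Eprs, by 3.26-fold to 5.99-fold. Mcmdc2 stood at 3.99 CPM in DG neurons with THC, near the median of 3.67 CPM of the remaining 3 libraries, so transgenic vehicle was the library apart for it. It was also the one apart for F13a1 and Dnase1l2 in DG neurons, Clstn1, Fth1, Hjurp and Orc4 in astrocytes, Stimate, Tmbim6, Myef2 and Snx12 in oligodendrocytes, and Atp6v1h, Zfp322a, Atp6v0c and Eprs in microglia. Near 0 with vehicle in 1 class were Fth1, Stimate, Myef2, Atp6v1h and Zfp322a. Snx12 lies on the X chromosome, and sex makeup differed between these libraries. Egr1 of CA1 neurons stood at 19.0 CPM in wild type, close to transgenic vehicle.

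THC held 44.3% and transgenic vehicle 96.6% nuclei with Xist alone. Over those nuclei, a setting chosen after seeing the data, the interferon response median was 0.20 in place of -0.17, and without doublet removal that of homeostatic astrocyte genes was -0.12 in place of 0.19.

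The third comparison, celecoxib against vehicle in transgenic mice, asked what the cyclooxygenase-2 inhibitor alone goes with. Glia were more frequent in this library. So were choroid plexus cells, 1.65-fold (1.29 to 2.11), and fibroblasts, 2.85-fold (1.49 to 5.82) at 39 against 13 nuclei. The fibroblast values leave out an unnamed cluster with markers of fibroblasts and mural cells, which held 139 nuclei in celecoxib and 50 with vehicle. Microglia made up 7.05% of nuclei (6.43% to 7.71%), 1.51-fold more (1.30 to 1.76), oligodendrocytes 11.2%, 1.84-fold more (1.62 to 2.10), and astrocytes 7.92%, 1.25-fold more (1.09 to 1.43). Inhibitory neurons were 1.67-fold fewer (1.46 to 1.90), or 1.36-fold fewer (1.19 to 1.57) without 1 cluster that held 26 nuclei in celecoxib and 144 with vehicle, a setting chosen after seeing the data, and CA1 neurons 1.31-fold fewer (1.18 to 1.46). Disease-associated microglia genes had a median of 0.18 (0.08 to 0.34), with 4 of 28 higher and 0 lower, at percentile 99.9 of random lists. Meg3 stood in these microglia at 4.97 CPM (1.02 to 14.5), against 29.3 CPM (14.6 to 52.4) with vehicle. Among the higher list members was the growth factor Igf1 at 282 against 170 CPM.

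Activity-induced genes differed between neuron types. In CA1 neurons they had a median of -0.57 (-0.69 to -0.29), with 5 of 16 lower and 0 higher. The shallow cluster made up 8.97% of these neurons, and without it, a setting chosen after seeing the data, the median was -0.41. Egr1 was 3.26-fold lower (2.22 to 5.02) at 5.57 CPM, Npas4 stood at 3.38 and Arc at 3.04 CPM. In DG neurons they had a median of 0.34 (0.09 to 0.60), with 3 of 12 higher. Nr4a2 stood at 9.37 against 3.20 CPM, Nr4a3 at 5.57 against 1.60 CPM and Inhba at 60.0 against 35.9 CPM. Cholesterol synthesis genes of astrocytes had a median of 0.37 (0.10 to 0.65), with 3 of 14 higher and Sqle at 33.6 against 5.26 CPM, the latter near 0, beside Meg3 at 20.0 CPM (12.5 to 30.3) against 10.5 CPM (4.54 to 20.7). Disease-associated astrocyte genes had a median of 0.12, with Apoe 1.64-fold higher at 1471 against 897 CPM and C4b 1.52-fold lower (1.29 to 1.79). Prostaglandin genes had medians of 0.53 in DG, 0.25 in CA1, 1.24 in astrocytes and -0.06 in microglia, and Ptger4, a prostaglandin receptor gene, stood at 14.2 against 8.58 CPM in DG neurons.

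Homeostatic microglia genes had a median of -0.06, complement genes of -0.03, inflammatory genes of -0.14, interferon response genes of 0.0088 and antigen presentation genes of 0.07. Homeostatic astrocyte genes had a median of -0.28, disease-associated oligodendrocyte genes of -0.21, and myelin genes of 0.0029. Glutamatergic synapse genes had medians of -0.11 in DG and -0.10 in CA1 neurons, presynaptic genes of -0.03 and -0.09, and amyloid precursor processing genes of 0.02 and -0.12. Endocannabinoid genes had medians of -0.10 in DG, -0.06 in CA1, 0.27 in inhibitory neurons, 0.29 in astrocytes and -0.35 in microglia. Cnr1 stood at 219 CPM in inhibitory neurons, against 121 CPM with vehicle, a class whose mix of clusters differed, and without the uneven cluster it stood at 229 against 136 CPM. Cholesterol synthesis genes of oligodendrocytes had a median of 0.11, beside Meg3 at 3.27 CPM (0.891 to 8.37) against 77.7 CPM (57.5 to 103). This Meg3 value with celecoxib, of 4 UMIs, was itself near 0 in 1 class of 1 library. Oxidative phosphorylation genes had medians of 0.07, -0.05, 0.15, 0.08 and 0.51 in DG, CA1, astrocytes, oligodendrocytes and microglia, and heat shock genes of -0.20, -0.14, 0.42, 0.30 and 0.40.

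By the naming rule, Gm48027, Gm21798 and Enpp5 were higher in DG neurons by 2.31-fold to 2.76-fold, and Dpm3, Gm20700 and Gm47371 in CA1 neurons by 3.00-fold to 3.67-fold. Gm17167, a transcript without a known protein (ENSMUSG00000091542, chromosome 4, 42206998 to 42235313), was 4.46-fold lower in DG (3.23 to 6.35) and lower in CA1 neurons. Mcmdc2 was lower in both and Dnase1l2 in DG neurons. Glial genes higher with celecoxib rested on few counts with vehicle. In astrocytes these were Rragb at 54.5 CPM (41.6 to 70.2), Nploc4 and Herc3, with 1, 1 and 3 UMIs with vehicle. In oligodendrocytes these were Abca5, Nol8 and Dtd1, and in microglia Napg and Fam126b, with 1 UMI each, and Rab3gap2. Rragb, Herc3, Abca5 and Rab3gap2 with vehicle were near 0 in 1 class of 1 library, as was Gm17167 in CA1 neurons with celecoxib, so no fold is given for them. Lower were Hjurp, Tmem189 and Csnk1d in astrocytes, Katnbl1, Gatb and Golph3 in oligodendrocytes, and Sec62, Mkrn1 and Golph3l in microglia, by 2.34-fold to 4.04-fold. Transgenic vehicle was the library apart for all of these genes but Gm17167, Dpm3, Gm47371, Nol8, Katnbl1, Golph3, Fam126b, Sec62 and Golph3l.

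Celecoxib held 75.4% and transgenic vehicle 96.6% nuclei with Xist alone. Rragb, named above, lies on the X chromosome. With a minimum of 1000 genes, the median of disease-associated microglia genes was 0.03 and that of astrocyte cholesterol genes 0.06.

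The fourth comparison, celecoxib and THC against vehicle in transgenic mice, asked what the drugs together go with. Cholesterol synthesis genes of astrocytes were higher, with a median of 1.25 (0.94 to 1.58), 11 of 16 members higher and 0 lower. Meg3, a neuronal marker, stood in these astrocytes at 70.6 CPM (50.7 to 95.8), against 10.5 CPM (4.54 to 20.7) with vehicle, while Snap25 had 1 UMI against 3. Hmgcs1 was 3.45-fold higher (2.22 to 5.66) at 124 against 35.5 CPM, and Sqle stood at 44.8 against 5.26 CPM, the latter near 0. Heat shock and unfolded protein genes had a median of 1.28 (0.62 to 1.89) in astrocytes, with 5 of 9 higher, and one of 0.75 (0.35 to 1.18) in oligodendrocytes, with 4 of 10 higher. In microglia interferon response genes had a median of -0.66 (upper bound -0.42), with 5 of 14 lower and 0 higher, and antigen presentation genes had a median of -0.79 (-1.15 to -0.34), with 2 of 7 lower. The astrocyte marker Slc1a2 stood in these microglia at 36.6 CPM (20.0 to 61.4) against 7.98 CPM (1.65 to 23.3), and Meg3 at 10.5 CPM (2.85 to 26.8) against 29.3 CPM (14.6 to 52.4).

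Among the interferon genes, Ifi204 stood at 49.7 against 122 CPM and Sp100 at 136 against 208 CPM. H2-D1, a class I antigen presentation gene, stood at 52.3 against 114 CPM. Disease-associated microglia genes had a median of -0.13, with 2 of 27 higher and 2 lower. The receptor gene Axl stood at 222 against 144 CPM, and Tyrobp was 2.41-fold lower (1.65 to 3.62). Microglia made up 4.83% of nuclei (4.28% to 5.42%), 1.03-fold the share with vehicle (0.871 to 1.23). Disease-associated astrocyte genes had a median of -0.28 (-0.48 to -0.11). Gfap was 1.61-fold lower (1.35 to 1.92), while Apoe was 1.67-fold higher (1.51 to 1.85) and Clu 1.95-fold higher (1.60 to 2.38). As by genotype, these class ratios set different mixes of astrocyte clusters side by side.

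In CA1 neurons Egr1 was 3.38-fold lower (2.29 to 5.23) at 5.38 CPM, and activity-induced genes had a median of -0.06 with 5 of 16 lower. In DG neurons they had a median of 0.27, with Homer1, a postsynaptic scaffold gene, at 95.3 against 62.2 CPM. Presynaptic release genes had medians of 0.02 in DG and 0.14 (0.05 to 0.20) in CA1 neurons, where the fusion gene Cplx2 stood at 40.7 against 24.8 CPM. Oxidative phosphorylation genes of CA1 neurons had a median of -0.29 (-0.43 to -0.17), with 5 of 21 lower, and Ndufa4 at 3.87 against 9.02 CPM.

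Homeostatic microglia genes had a median of -0.11, complement genes of -0.27 and inflammatory genes of -0.18. Homeostatic astrocyte genes had a median of 0.13, disease-associated oligodendrocyte genes of -0.15 and myelin genes of 0.05. Glutamatergic synapse genes had medians of 0.02 and 0.04 in DG and CA1 neurons, and amyloid precursor processing genes of 0.04 and -0.11. Endocannabinoid genes had medians of 0.0097, -0.06, -0.04, 0.05 and 0.0043 in DG, CA1, inhibitory neurons, astrocytes and microglia. Prostaglandin genes had medians of 0.14, -0.23, -0.06 and -0.02 in DG, CA1, astrocytes and microglia. Cholesterol genes of oligodendrocytes had a median of 0.06 over 3 members. Oxidative phosphorylation genes had medians of -0.16, 0.01, 0.52 and 0.25 in DG, astrocytes, oligodendrocytes and microglia, and heat shock genes of -0.05, 0.10 and 0.11 in DG, CA1 and microglia.

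By the naming rule, Atp6v0c was 4.73-fold higher in DG neurons (3.51 to 6.59), much as with THC alone, and Rnasek stood at 8.67 against 1.45 CPM. Gm42418, a noncoding transcript (ENSMUSG00000098178, chromosome 17, 39846958 to 39848788), was 3.14-fold higher in DG (2.98 to 3.31) and 2.28-fold higher in CA1 neurons. In DG neurons Lgr6, a receptor gene (ENSMUSG00000042793, chromosome 1, 134983301 to 135105276), stood at 5.28 CPM (3.76 to 7.22) against 44.6 CPM (39.8 to 49.9), and Cyp11a1, a steroid-forming enzyme (ENSMUSG00000032323, chromosome 9, 58006411 to 58027023), at 2 UMIs against 8.43 CPM (6.40 to 10.9). In CA1 neurons Gm21887 and Pcsk1 were higher and Rdh14 lower, and Mcmdc2 was lower in both neuron types. Higher were Rcor3, 4732471J01Rik and Usp3 in astrocytes, Tmbim6, Hdx and BC002059 in oligodendrocytes, and Ap3s1, Pspc1 and Farsb in microglia. Lower were Kdm6a, Tor1aip2 and Nr6a1 in astrocytes, Snx12, Pcnp and Sf3b3 in oligodendrocytes, and Eprs, Cpsf7 and Cpd in microglia. Near 0 in 1 class of 1 library were Lgr6, Cyp11a1, Kdm6a, Tor1aip2, Pcnp and Sf3b3 with both drugs and Rcor3, Hdx and Pspc1 with vehicle. Kdm6a lies on the X chromosome and stood at 36.2 against 218 CPM. Snx12, Hdx and Gm21887 lie on the X chromosome too. Transgenic vehicle was the library apart for Gm42418 and Mcmdc2 in both neuron types, Rcor3, 4732471J01Rik and Usp3 in astrocytes, Tmbim6, Hdx, BC002059 and Snx12 in oligodendrocytes, and Pspc1 and Eprs in microglia.

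Celecoxib and THC held 0.0542% and transgenic vehicle 96.6% nuclei with Xist alone, so treatment and sex makeup could not be parted in this comparison. Without doublet removal the cholesterol median in astrocytes was 0.80 and that of disease-associated astrocyte genes -0.51.

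**Figure D3:**
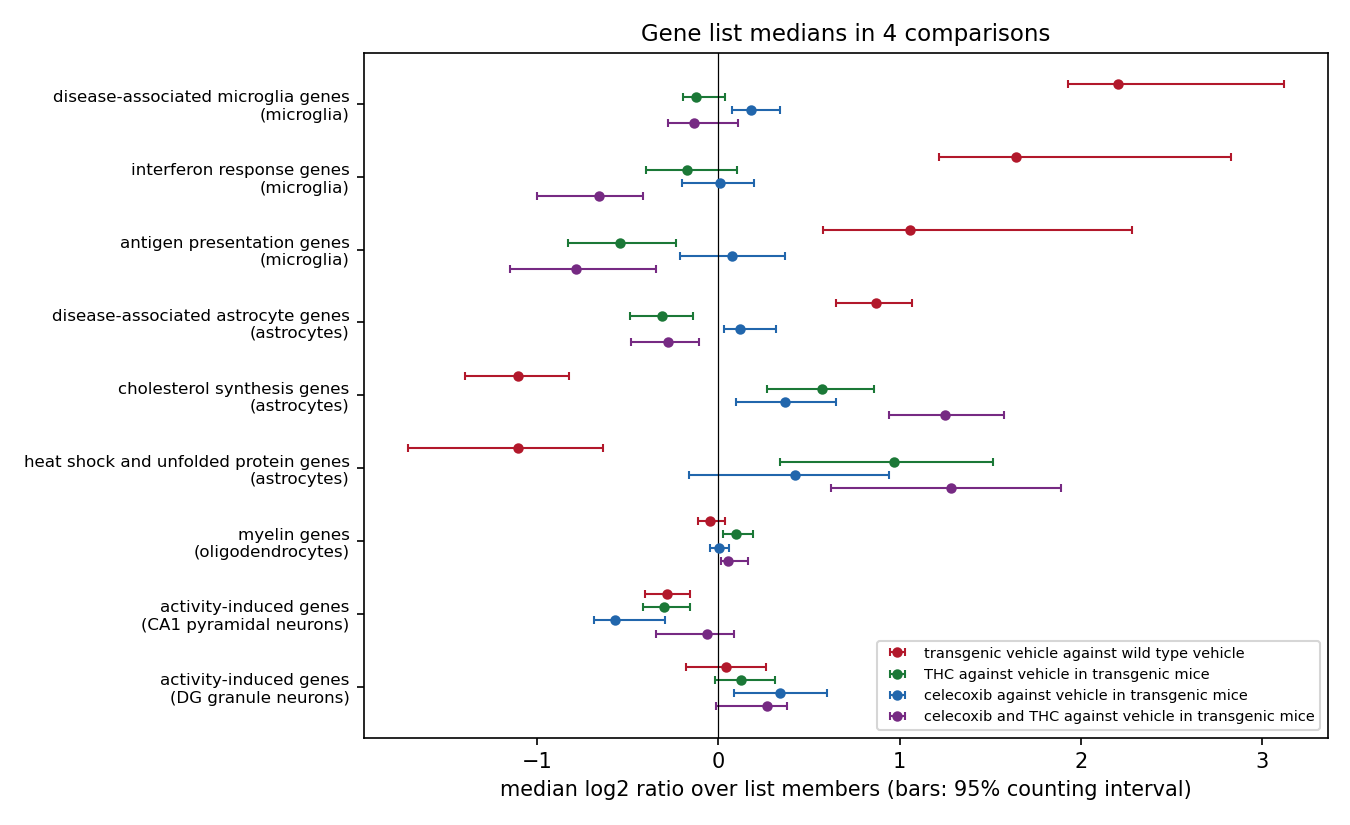
Median log2 ratio on the horizontal axis for 9 pairs of gene list and cell class, with 1 point per comparison and 95% counting intervals as bars. Shown are the 4 comparisons with a vehicle library. Disease-associated microglia genes sit at 2.20 by genotype and between -0.13 and 0.18 by treatment against vehicle, and astrocyte cholesterol genes at -1.10 by genotype and between 0.37 and 1.25 by treatment against vehicle. All 4 comparisons share the transgenic vehicle library. Low values in that library alone would give opposite signs by genotype and by treatment, so these signs show no reversal by the drugs.

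**Figure D4:**
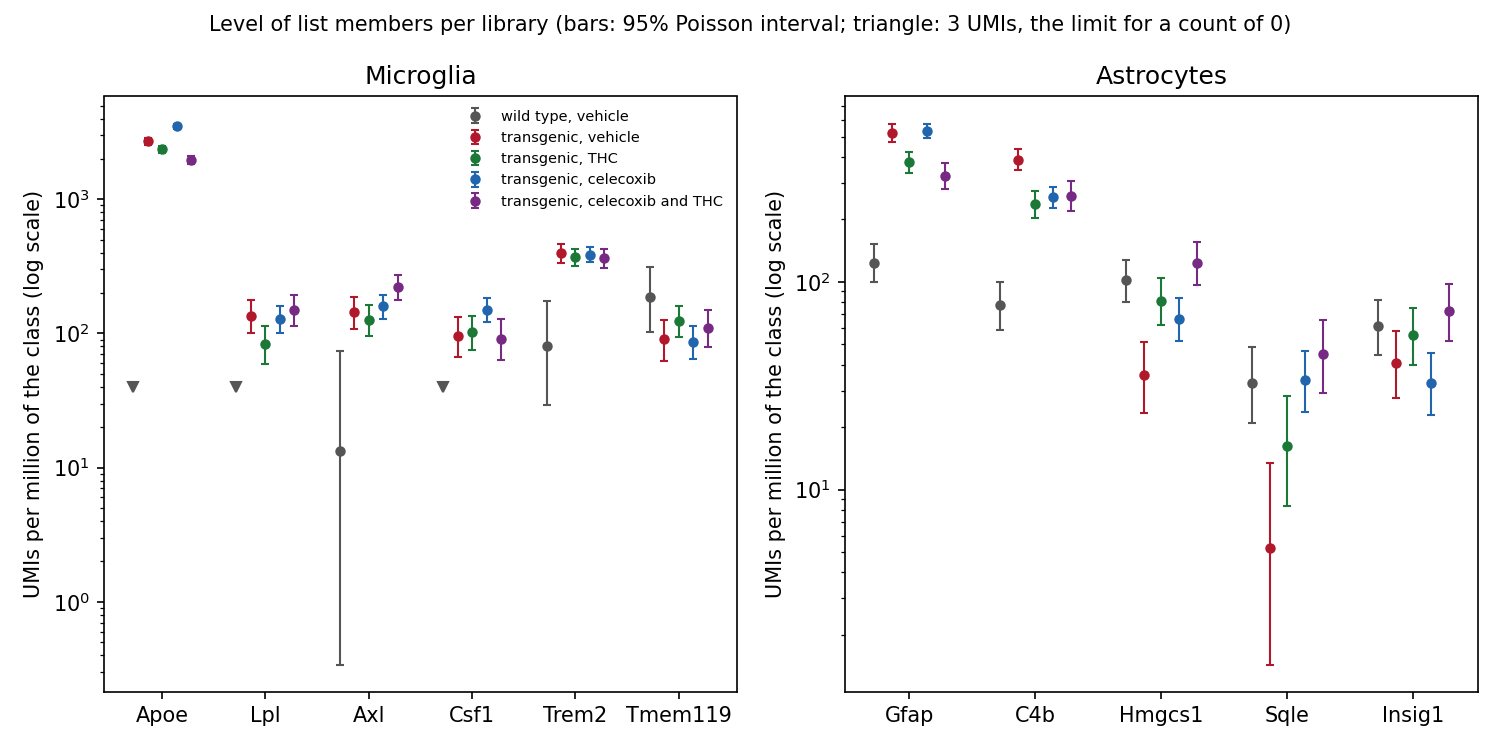
Level of list members in CPM on a log axis, in microglia and astrocytes, with 1 point per library and 95% Poisson intervals, and triangles at 3 UMIs for counts of 0. Microglial Apoe stood at 0 UMIs in wild type vehicle and between 1959 and 3516 CPM in the transgenic libraries.

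The last comparisons set celecoxib and THC against each drug alone. Against celecoxib, disease-associated microglia genes had a median of -0.26 (-0.45 to -0.10), with 10 of 28 lower and 0 higher, and interferon response genes one of -0.62 (-0.93 to -0.42), with 5 of 15 lower and 0 higher. Antigen presentation genes had a median of -0.77 with 5 of 9 lower. Slc1a2 stood in these microglia at 36.6 CPM (20.0 to 61.4), against 0 UMIs (up to 6.11 CPM) with celecoxib and 4.26 CPM (0.516 to 15.4) with THC. In astrocytes cholesterol synthesis genes had a median of 0.86 with 11 of 16 higher, beside Meg3 at 70.6 against 20.0 CPM, homeostatic genes of 0.42 with 5 of 17 higher, disease-associated genes of -0.30 and heat shock genes of 1.02. Against THC, interferon response genes had a median of -0.50 (-0.81 to -0.26), astrocyte cholesterol genes of 0.60 with 4 of 15 higher, beside Meg3 at 70.6 against 1.35 CPM, and disease-associated microglia genes of -0.13. The Meg3 value of 1.35 CPM was near 0 in 1 class of 1 library.

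Activity-induced genes of CA1 neurons had medians of 0.03 against THC and 0.25 against celecoxib. Without doublet removal the median against celecoxib took the other sign. Against THC the first named genes were Wbp11 (63.2 against 20.7 CPM) and Lgr6 (5.28 against 30.8 CPM) in DG, Gm31508 and Epyc in CA1 neurons, Gm29683 and Kdm6a in astrocytes, Zfp40 and Pcnp in oligodendrocytes, and Ap3s1 and Ggps1 in microglia, the first of each pair higher. Against celecoxib they were Rnasek and Cyp11a1 in DG, Gm17167 and Zfp867 in CA1 neurons, Gm42418 and Slc25a40 in astrocytes, Gm42418 and Zfp26 in oligodendrocytes, and Gm42418 and Napg in microglia. Slc25a40 stood at 0 UMIs in astrocytes of the combination and Zfp26 at 0 in oligodendrocytes. These 2 values, those of Lgr6, Cyp11a1, Kdm6a, Pcnp, Ggps1 and Zfp867 in the combination, and those of Rnasek and Gm17167 with celecoxib were near 0 in 1 class of 1 library, so no fold is given. Over nuclei with Y-linked UMIs alone, a setting chosen after seeing the data, the interferon response median against THC was 0.03 in place of -0.50. With members of at least 50 UMIs the heat shock median against celecoxib was -0.18.

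Genes that differed by genotype were then followed into the treated libraries. In astrocytes, 77 genes lower in transgenic vehicle, with a median log2 ratio to wild type of -1.01, had medians against the other part of that library of 0.55 with THC, 0.73 with celecoxib and 0.57 with both. In oligodendrocytes, 86 lower genes had medians of 0.21, 0.66 and 0.34. The 81 astrocyte genes higher in transgenic vehicle had medians of -0.29, 0.08 and -0.29, and the 45 of oligodendrocytes -0.27, -0.13 and -0.30. In microglia, 91 higher genes had medians of -0.06, -0.09 and -0.10 and 38 lower genes 0.20, 0.16 and 0.13. In DG neurons, 27 higher genes had medians of -0.07, 0.20 and -0.15 and 25 lower genes 0.37, 0.34 and 0.23. In CA1 neurons, 49 higher genes had medians of 0.01, 0.21 and -0.04 and 34 lower genes -0.05, -0.07 and 0.14. A state particular to the transgenic vehicle library stays shared by both of its parts. With an unsplit reference the medians of higher genes in DG neurons were -0.44, -0.33 and -0.35. With the wild type library split too, a setting chosen after seeing the data, the ratio to wild type was -0.53 for 33 lower genes of astrocytes and 0.25 for 31 higher genes of DG neurons, in place of -1.01 and 0.80. Lower genes of CA1 neurons then had 0.17 with THC and 0.18 with celecoxib, of the other sign, lower genes of microglia had -0.057 with THC and -0.052 with celecoxib, those of astrocytes 0.22 with THC and those of oligodendrocytes 0.079 with both drugs.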

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

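The tests on Lgr6, Cyp11a1 and Wbp11 in this part were chosen after their values were seen. RNA of 4 Y-linked genes, which no comparison uses, stood in 4 libraries above the interval of transgenic vehicle, at 0.148 CPM (0.0482 to 0.346), and no label gives a sex. It reached 241 CPM in wild type vehicle. In transgenic THC it was 212 CPM. In transgenic celecoxib it was 95.4 CPM. In transgenic celecoxib and THC it was 366 CPM. Xist of transgenic vehicle stood at 1168 CPM against 1.07 CPM in celecoxib and THC.

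Lgr6, Cyp11a1 and Wbp11 stood apart in DG granule neurons of single libraries, Lgr6 and Cyp11a1 low in celecoxib and THC and Wbp11 low in THC. An effect of sex that is the same in all libraries is argued against for Lgr6 and Wbp11. Nuclei with Y-linked UMIs had a log2 ratio to nuclei with Xist of 0.84 for Lgr6 in wild type (lower bound 0.46). For Wbp11 it was 1.11 in celecoxib but -0.14 in wild type. In THC the Lgr6 ratio was -2.13, so an effect of sex on Lgr6 in transgenic mice alone is not excluded. For Cyp11a1 sex cannot be told apart, since the ratio was -3.85 in wild type and -3.46 in THC but 0.46 in celecoxib (lower bound -0.58). A candidate explanation is that animals pooled in a library differ, since for all 3 genes the nuclei of both kinds in at least 1 library differed at least 2-fold, as for Lgr6 at -2.13 in THC. Nuclei of both kinds come from different animals, so within a library these ratios cannot part sex from other differences between animals. Removal of counts within a class before deposit cannot be told apart for Lgr6 and Cyp11a1, since in 0 other classes of celecoxib and THC were 20 UMIs of either expected, and the treatments stay open and untested.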

How the results depend on the processing

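The settings over nuclei with Xist alone, over nuclei with Y-linked UMIs alone, without members near 0, without the shallow clusters, without the uneven inhibitory cluster and with the wild type library split too were chosen after seeing the data. Scaling had little effect: under median-of-ratios size factors 134 of the log2 ratios of named genes and 250 list medians stayed within their intervals and 14 medians moved. Leaving out members near 0 kept 224 medians within their intervals. For the values below the cause was not tested unless stated. The subtraction of an empty-droplet profile was not run, since 6203 to 8134 barcodes per library held counts and gave no empty-droplet profile. The number of genes past the size rule and its alternatives were not run, since 1 library per group gives no count of changed genes.

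With a minimum of 1000 genes the microglial share was 0.632% in wild type vehicle, 2.01% in transgenic vehicle, 2.43% in THC, 3.39% in celecoxib and 2.14% in celecoxib and THC. With no doublets removed it was 1.51%, 6.02%, 6.97%, 8.67% and 5.91%, and at resolution 2 it was 5.45% in transgenic vehicle, 8.22% in celecoxib and 5.48% in celecoxib and THC. The share of CA1 neurons at resolution 2 was 10.4% in wild type vehicle, 8.02%, 7.81%, 5.56% and 7.23%. Inhibitory neurons without the uneven cluster made up 6.95%, 7.69%, 5.62%, 5.63% and 6.56%, and their endocannabinoid median with THC was 0.24. Without the shallow clusters the glutamatergic synapse median by genotype was -0.061 in DG and -0.11 in CA1 neurons, and that of both drugs against celecoxib was 0.065 in DG neurons.

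With a minimum of 1000 genes the disease-associated microglia median was 1.83 by genotype and 0.030 with celecoxib, the interferon median with THC 0.11, and the astrocyte cholesterol median -0.79 by genotype and 0.055 with celecoxib. With no doublets removed the disease-associated microglia median was 1.67 by genotype and 0.38 with celecoxib, the interferon median with celecoxib 0.25, the disease-associated astrocyte median -0.54 with THC and -0.51 with both drugs, the activity-induced CA1 median with THC -0.47 and the cholesterol median with both drugs 0.80. Reversed there were homeostatic astrocyte genes with THC at -0.12 and activity-induced CA1 genes of both drugs against celecoxib at -0.0027. As a mean over nuclei the disease-associated astrocyte median with THC was -0.61. With members of at least 50 UMIs the astrocyte heat shock median of both drugs against celecoxib reversed to -0.18. Over nuclei with Xist alone the interferon median with THC was 0.20, and by genotype the disease-associated astrocyte median was 0.62, the cholesterol median -0.76 and the activity-induced CA1 median 0.20, reversed. Over nuclei with Y-linked UMIs alone the interferon median of both drugs against THC reversed to 0.028.

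For genes that differed by genotype, an unsplit reference shares its counting error with the choice of genes. Simulated libraries without effect then gave medians of -0.344 for higher genes of DG neurons and -0.312 for those of microglia. When split they gave -0.024 and -0.028. The microglial run used class totals of transgenic vehicle and THC, not of wild type. These medians show the direction of this bias and not its size in the libraries. Values follow for THC, celecoxib and both drugs. Unsplit, higher genes had -0.12, 0.043 and -0.38 in CA1, -0.44, -0.33 and -0.35 in DG (celecoxib reversed), -0.47, -0.15 and -0.55 in astrocytes, and -0.50, -0.26 and -0.61 in oligodendrocytes. Higher genes of microglia had -0.17 with celecoxib and -0.16 with both drugs. Lower genes had 0.30, 0.16 and 0.47 in CA1, 0.70, 0.63 and 0.73 in DG, and 0.76, 1.02 and 0.76 in oligodendrocytes. Lower genes had 0.80 with THC and 0.97 with celecoxib in astrocytes, and 0.34 and 0.33 in microglia. With the wild type library split too, lower genes had 0.17, 0.18 and 0.32 in CA1 and 0.20, 0.46 and 0.079 in oligodendrocytes. They had 0.10 with THC and 0.14 with celecoxib in DG, 0.22 and 0.485 in astrocytes, and -0.057 and -0.052 in microglia, both reversed. In both settings the sign also turned, from medians with an interval spanning 0, for lower CA1 genes with THC and celecoxib, higher CA1 genes with THC and higher astrocyte genes with celecoxib. Higher genes of astrocytes had -0.21 with both drugs.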

Other observations

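Apart from the cholesterol test under median-of-ratios scaling, the tests in this part were chosen after the results were seen, as were the genes of the first 2 paragraphs. CA1 neurons of all 4 transgenic libraries held more RNA of the cholesterol synthesis gene Hmgcs1 than those of wild type, opposite to the astrocytes of transgenic vehicle. It stood there at 11.5 CPM (8.77 to 14.8) in wild type and at 38.0, 44.4, 43.4 and 49.4 CPM in transgenic vehicle, THC, celecoxib, and celecoxib and THC. In inhibitory neurons Hmgcs1 stood at 18.1, 17.4, 25.2, 18.7 and 23.3 CPM in the 5 libraries. Hspa5, the main chaperone of the endoplasmic reticulum, was higher in both libraries with THC in CA1 and inhibitory neurons. In CA1 neurons it stood at 11.7, 6.89, 26.1, 7.94 and 22.0 CPM in wild type vehicle, transgenic vehicle, THC, celecoxib, and celecoxib and THC, and in inhibitory neurons at 19.9, 22.0, 41.7, 22.4 and 45.1 CPM. In oligodendrocytes it stood at 28.0, 23.8, 72.3, 47.4 and 56.3 CPM, and there it was also 1.94-fold higher with celecoxib alone (1.11 to 3.79). Apoe of oligodendrocytes stood at 97.9, 108, 351, 190 and 378 CPM in the same order.

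Less frequent cell classes differed as well. Endothelial cells, which line blood vessels, made up 1.05% of nuclei (0.818% to 1.34%) in celecoxib and 0.282% (0.164% to 0.451%) in transgenic vehicle, 3.74-fold more (2.17 to 6.80). Oligodendrocyte precursors made up 2.72% in celecoxib, 1.79-fold more than with vehicle (1.38 to 2.33). Choroid plexus cells made up 2.93% in celecoxib and 1.77% in transgenic vehicle. Fibroblasts of the named cluster, without the larger unnamed one, made up 0.614% and 0.215%. Ependymal cells made up 0.197% in wild type vehicle, 0.530% in transgenic vehicle, 0.555% in THC, 0.787% in celecoxib and 0.163% in celecoxib and THC. Thalamic or habenular neurons, which lie next to the hippocampus, made up 0.743% in wild type vehicle and 0.904% in celecoxib and THC, and 0.315%, 0.236% and 0.236% in transgenic vehicle, THC and celecoxib. Nuclei of a shallow cluster made up 52.2%, 51.5%, 32.3%, 25.2% and 41.5% of DG granule neurons in the 5 libraries, and those of another 39.9%, 20.5%, 15.4%, 8.97% and 24.3% of CA1 neurons. Without them the activity-induced median of CA1 neurons was -0.38 by genotype, -0.19 with THC, -0.41 with celecoxib and -0.051 with both drugs.

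Some genes fell near 0 in 1 cell class of 1 library: with at least 20 UMIs expected there from the other libraries, 575 stood under 0.2 of the median of the other 4 libraries and 6 stood over 5-fold above it. For genes near 0 in glia, the median ratio in the other classes of that library was 0.992 (quartiles 0.887 to 1.09), which argues against a difference of its animals shared by all classes. For genes near 0 in DG or CA1 neurons such a difference cannot be told apart, since the ratio was 0.929 (0.708 to 1.11) and fell to 0.225 for those of CA1 neurons in celecoxib, 0.685 for CA1 and 0.783 for DG neurons with both drugs and 0.715 for DG neurons with THC. A candidate explanation is that counts were removed gene by gene within a class before deposit, a step that no label records. Zfp26 in oligodendrocytes of celecoxib and THC, at 0 UMIs, and Apoe in microglia of wild type, also at 0 UMIs, are examples, and no biological explanation was tested.

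Cholesterol synthesis genes were lower in astrocytes of transgenic vehicle than of wild type, at a median of -1.10. Members near 0 in 1 library and scaling are argued against as the whole cause, since the median was -0.99 (-1.35 to -0.73) over the 15 members left and -1.13 (-1.42 to -0.83) with median-of-ratios size factors. Sex makeup cannot be told apart: over nuclei with Xist alone the median was -0.76 (-1.09 to -0.31) over 11 members, an interval that reaches past the bound of -0.5 set for it. The genotype stays among the open explanations, and so may a state particular to the animals of transgenic vehicle.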
